A study of Lactobacillus helveticus and Lactobacillus helveticus DPC 4571 and Lactobacillus helveticus CNRZ32 with 9 samples.

How the data were processed

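Genomic DNA of 9 strains of Lactobacillus helveticus was hybridised against DNA of the strain DPC4571 on 2-colour arrays, with 1 sample per strain and 2 arrays per sample. Per the labels' protocols, DNA was sheared by sonication and labelled with Klenow polymerase and random primers, with Cy3 on the test strain and Cy5 on DPC4571, and the arrays held 2164 ORFs. The labels give no dye swap, so dye bias of single ORFs cannot be separated from a difference to DPC4571 that all 9 test strains share.

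The authors deposited 36 scanner files, 1 per channel and array, whose values are linear spot intensity before any normalization. Per the file headers they come from a spot-reading program with fixed-circle segmentation that marks empty, poor and negative spots. Scanner settings are not given in the sources used here. The authors also deposited a table of 2164 rows with 1 log2 ratio per strain. Its method of normalization and its filter are not given in the sources used here. Its scale and direction were found by setting windows of 40 rows beside the scanner values. In 30 of 54 windows the correlation reached 0.5 at some place in the array numbering. Each place was that of the highest correlation, so the median slope of 0.92 was positive by construction. Taken over selected windows, it is only a rough guide to scale. Direction was taken from the order of the places, which rose along the table in 96.6% of steps. The table was read as log2 of test over reference, in the order of its locus tags. Its column medians ran from −0.28 to 0.04 and its missing values from 1 to 1421 per strain, so what it was centred on stays unknown. The files do not pair its rows with the identifiers on the array, and positions in the table and on the array are separate numberings.

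Spots that were marked in either channel, empty positions and control spots were left out. For each remaining spot log2 of test over reference signal mean was taken with no background subtraction, averaged per ORF and centred on the array's median, with no loess or quantile step, as is usual for genomic DNA. ORFs were kept where the reference signal was at least 2 times local background on at least 9 of the 18 arrays, which left 2162. An ORF was lower in a strain where both arrays were at or under −1 and higher where both were at or above 1. Between 1325 and 2084 ORFs per strain were measured on both arrays. Between 1.92% and 52.8% of ORF spots were marked on an array, so counts are over measured ORFs. Before centring the median log2 ratio of an array ran from −1.99 to 0.39. On the CNRZ32 arrays the spot grids of the 2 channels were offset by 3.49 on array 1, in the coordinates of the files, and 27 spots of array 2 lacked a value in a channel.

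Shares of measured ORFs carry Wilson 95% intervals. Runs of 3 or more adjacent lower ORFs were counted over kept ORFs in the array's numbering and set against 10000 shuffles of ORF position, the same shuffle for all strains, one-sided. Overlapping runs of different strains were merged into regions, and the mean log2 ratio of a region in a strain is over its measured ORFs. Pairs of strains were compared by shared lower ORFs, beside the number that independent lists of those sizes would share, and by Jaccard index, over the ORFs measured in both. Across the 9 strains the mean of the 2 arrays was tested against 0 with limma (lmFit and eBayes) in ORFs with values in at least 5 strains, with Benjamini-Hochberg adjustment, at adjusted p under 0.05 and a mean of at least 1 in size. As a background, the reference channels of each pair of strains were set against each other, array 1 with array 1 and array 2 with array 2, by the same rule. Each region that had a mean compared between channels was taken relative to the array's median over ORFs.

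The rule for single ORFs, fixed before the data were examined, took the 12 lowest by mean among those called lower and under 0 in all 9 strains and the 5 highest among those called higher, then the lowest ORFs of each strain and the ends of the longest runs. It also listed genes of proteolysis, sugar use and restriction by name. Since the files do not pair identifiers with names, the text gives identifiers for few ORFs of the test across strains. These are the 2 lowest among those under 0 in all 9 strains and the 2 highest, and the rest is described as regions. Gene groups by product, fixed before the data were examined, were not tested for the same reason, and the annotation was not used here.

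Alternatives fixed before the data were examined were background subtraction, normexp with an offset of 50, loess within arrays, centring on the mode, the deposited table, thresholds of 1.5 and 0.75, the mean of the 2 arrays, no filter and a filter at 4 times background, marked spots kept, values relative to each ORF's median over strains, and each array alone. For the test across strains they were leaving out each strain, treat at 0.5, the 18 arrays with strain as a random block (duplicateCorrelation, correlation 0.871, and 0.851 with the identical arrays of DPC5607 counted as 1) and an exact sign-flip permutation test. Runs of 2 or 5 and more were also counted. Arrays with identical values were to be counted as 1 array, which leaves the counts of DPC5607 and its mean as they are. Ranges over 16 or 18 arrays list both arrays of DPC5607. Added after seeing the data were the foreground median of a spot, leaving out CNRZ32, DPC5607 or DPC5352, ORFs measured in all 9 strains only, and the day of measurement in the headers as a block or as a split of strain pairs, although the weekday in 26 of 36 headers is not that of the date.

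The calling rule was tested on simulated arrays of 2164 ORFs. It recovered 91.5% of ORFs set to a log2 ratio of −1.5 and 100% of those set to −3. Of unchanged ORFs, 0% were called. The simulated noise was Gaussian, independent between arrays and sized from duplicate spots, so this 0% is no estimate of false calls in the data. Reference channels set against each other gave 1 to 176 calls per pair and direction. The limma step, tested on 2159 simulated ORFs, called 100% at both sizes and 0% of unchanged ORFs. The simulated spread had an SD of 0.384 at both sizes and in unchanged ORFs. In the data OBSca009#0629, called lower, had a standard error of 0.384 over 9 strains, and a standard error is smaller than its SD. Low ORFs can thus vary more between strains than was simulated, so this 100% is no estimate of recovery in the data. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.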

Results

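Genomic DNA of 9 strains of Lactobacillus helveticus, a lactic acid bacterium used as a starter or adjunct culture in cheese making, was compared with genomic DNA of the strain DPC4571 on spotted microarrays of 2164 open reading frames (ORFs). The test strains were CNRZ32, DPC5352, DPC5360, DPC5364, DPC5365, DPC5367, DPC5389, DPC5394 and DPC5607. Test DNA carried Cy3 and DPC4571 DNA carried Cy5 on every array, so a log2 ratio below 0 means less signal from the test strain. Each strain was 1 sample, for which the labels name 2 arrays and also speak of 4 replicates of the hybridisation; 2 arrays per strain were analysed. Each array held 4608 spots with every ORF spotted in 2 copies. With 1 sample per strain there was no replicate check of a strain's count and no p-value per strain, and agreement between the 2 arrays is given instead. Median signal over local background was 8.32 to 56.7 in the test channel and 8.002 to 25.2 in the reference channel of the 18 arrays, and the number of arrays limits the precision. A low ratio does not by itself separate an absent ORF from one of diverged sequence or lower copy number. The files do not pair ORF identifiers with gene names, and ORFs are placed below by their number on the array (1 to 2164).

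The first question was how much of the DPC4571 gene set each strain carried. ORFs with lower signal than DPC4571, at least 2-fold on both arrays, were 11.2% of those measured in DPC5360 (179 of 1594, 95% Wilson interval 9.77 to 12.9%) and 10.65% in DPC5367 (211 of 1981). Shares were 8.53% in DPC5389 (113 of 1325), 7.99% in DPC5364 (129 of 1614), 7.85% in CNRZ32 (110 of 1402), 6.51% in DPC5352 (132 of 2028) and 6.29% in DPC5365 (131 of 2084, 5.32 to 7.41%). DPC5607 had 2.25% (44 of 1958, 1.68 to 3.00%) and DPC5394 1.63% (29 of 1775, 1.14 to 2.34%). The intervals cover counting error over ORFs only, and ORFs are not independent replicates. The share of DPC5394 was below those of the other 7 strains by this rule and under 15 of 15 alternatives, and that of DPC5607 under 11. The place of DPC5607 was lost with normexp (8.33%, lowest of the other 7 strains 6.29%), at a threshold of 0.75 (8.58% against 6.72%), relative to each ORF's median (1.79% against 1.49%) and in the deposited table (11.8% against 7.04%). In that table DPC5394 had 5.68% (112 of 1973) and DPC5389, with 743 values, 13.3%. CNRZ32 had the highest share of the 9 strains in that table (25.3%), by array 1 alone (17.3%) and by the mean of the 2 arrays (12.2%), and 2.57% after loess, so its rank is not settled. With marked spots kept, DPC5389 had the lowest share of the 7 strains other than DPC5394 and DPC5607 (5.64%). DPC5367 then had 8.65% and DPC5360 8.56%. The order among these 7 strains thus depends on the processing. The DPC5352 counts rest on a reference channel that differed from that of the other strains in ORFs 943 to 954 and 1186 to 1193. Which of these references departs from DPC4571 is not known. The median log2 ratio of a strain's lower ORFs was −2.71 in DPC5365 and −2.70 in DPC5352, against −1.22 in DPC5394 and −1.13 in DPC5607. ORFs with higher signal were fewer than lower ones by this rule, from 12 in DPC5365 and 19 in DPC5352 to 76 in CNRZ32 and 118 in DPC5367. This turned in DPC5394 (14 higher) and DPC5607 (38 higher) under other settings, in DPC5394 with 12 lower and 14 higher after loess, 8 and 9 at a threshold of 1.5 and 58 and 66 at 0.75. DPC5607 had 15 lower and 21 higher after loess, 8 and 10 at 1.5, 163 and 169 with normexp and 24 and 44 with marked spots kept. Relative to each ORF's median, these numbered 14 and 87 in DPC5394, 35 and 99 in DPC5607 and 31 and 31 in CNRZ32.

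**Figure D1:**
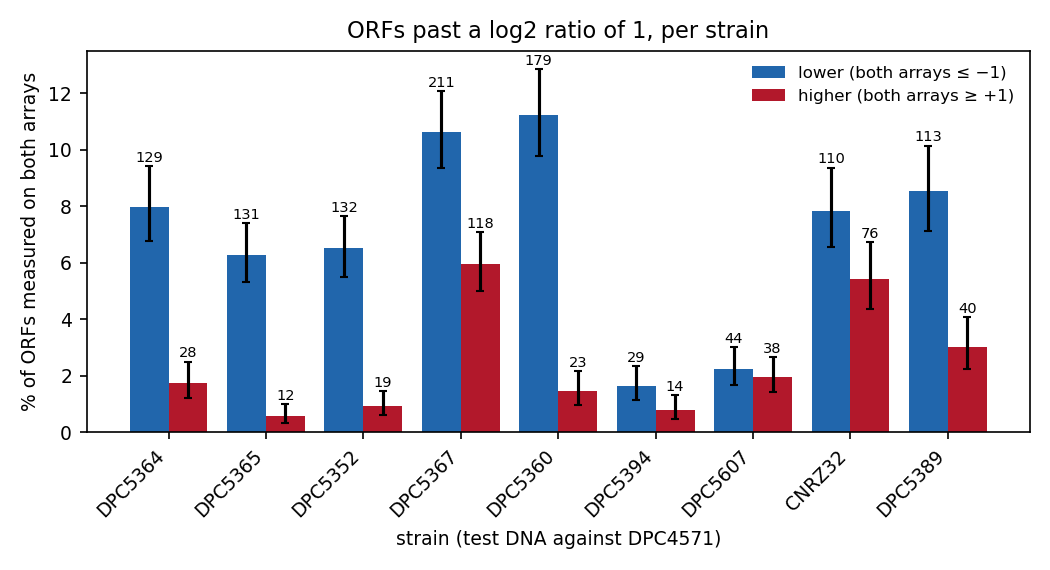
Percent of the ORFs measured on both arrays (vertical axis) that were lower or higher by a log2 ratio of 1 or more on both arrays, for each of the 9 strains. Bars carry 95% Wilson intervals and the number of ORFs, and the lower counts run from 29 in DPC5394 to 211 in DPC5367.

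How alike the arrays of a strain were differed between strains. The 2 arrays of DPC5607 held identical values in both channels at all 4608 spots, so its calls rest on 1 array. DPC5367's arrays were identical at 4320 spots (93.8%) and those of DPC5389 at 576 (12.5%). The counts of DPC5367 thus had almost no second array to pass, with 211 lower ORFs by both arrays and 214 by either alone. With 0 identical spots, the difference between the 2 copies of an ORF, test channel, correlated between arrays at 0.992 in DPC5365, 0.918 in DPC5352, 0.875 in DPC5364, 0.863 in CNRZ32, 0.595 in DPC5360 and 0.325 in DPC5394, so how far the second array was an independent check varied by strain. In the reference channel this correlation was 0.133 in CNRZ32, unlike its test channel, 0.760 in DPC5365 and 0.397 to 0.908 in the others of these strains. Across ORFs, which are not independent replicates, the correlation between a strain's arrays was 0.641 in CNRZ32 and 0.912 to 1.0 in the other 8. By array 2 alone CNRZ32 had 183 lower ORFs, by array 1 alone 245. On array 1, the second spot of an ORF was also lower for 20.3% of the ORFs lower by the first spot in DPC5607, against 93.7% in DPC5360.

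Over the 9 strains, 399 of 2162 ORFs (18.5%) were lower in at least 1 strain, against 830 in the deposited table and 622 at a threshold of 0.75. Of the 399, 177 were lower in 1 strain, 148 in at least 3 and 95 in at least 5. Of the 598 ORFs measured in all 9 strains, 439 (73.4%) were lower in none. ORFs lower in a single strain were most frequent in DPC5367 (58) and DPC5360 (52), and DPC5389 had 0. The 58 of DPC5367 come from arrays that were nearly identical, so a second array hardly filtered them. The ORFs lower in all 9 strains were numbers 256 (−2.81 to −1.25 over strains) and 257 (−3.48 to −1.13), named after their values were seen. Neither was lower in all 9 strains after loess within arrays, at a log2 threshold of 1.5 or relative to each ORF's median over the strains.

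Lower ORFs lay next to each other in the array's numbering. They formed 136 runs of 3 or more adjacent ORFs over the 9 strains, against a median of 4 and at most 22 in 10000 shuffles of ORF position (permutation test, one-sided p = 0.0001, the smallest these shuffles can give). The runs held 631 of the 1078 lower calls (58.5%). DPC5367 had 29 runs, DPC5360 24, DPC5365 21, DPC5364 19, DPC5389 16, DPC5352 13, CNRZ32 12, and DPC5394 and DPC5607 1 each. Overlapping runs merged into 42 regions of 231 ORFs in all, 14 with a run in 1 strain, 28 in at least 2 and 13 in at least 5. Taken relative to each ORF's median over the strains, which removes what most strains share, there were 48 runs.

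**Figure D2:**
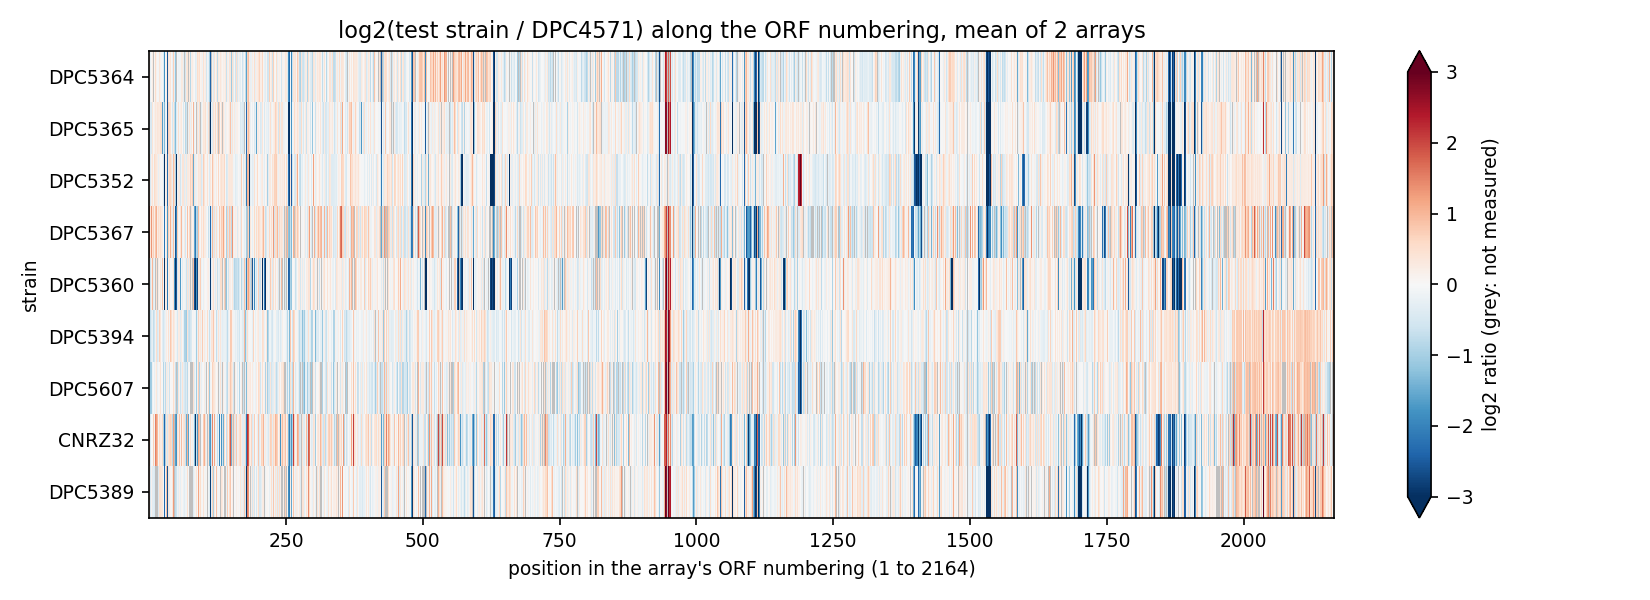
Log2 ratio of each test strain over DPC4571 (colour, mean of 2 arrays, grey where not measured) against ORF number on the array from 1 to 2164, with 1 row per strain. Blocks of low ratio recur at the same positions in several strains, and DPC5394 and DPC5607 each have 1 run of 3 or more lower ORFs.

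The largest region spanned ORFs 1392 to 1412 and was lowest in DPC5352 (mean log2 ratio −2.40), whose longest run covered 15 of its 21 ORFs. There CNRZ32 stood at −1.60, DPC5367 at −1.42, DPC5365 at −1.001 and the other 5 strains at −0.87 to −0.12. ORFs 1530 to 1537 had means of −3.91 to −2.24 in DPC5364, DPC5365, DPC5352, DPC5367, CNRZ32 and DPC5389, and of −0.15 to 0.05 in DPC5360, DPC5394 and DPC5607. ORFs 1861 to 1867 were low in the same 6 strains (−3.71 to −2.15), with the other 3 at 0.33 to 0.42. ORFs 1697 to 1704 were low in DPC5360 and 5 of those 6 (−3.70 to −1.72), and DPC5352, DPC5394 and DPC5607 stood at −0.36 to 0.16. ORFs 1876 to 1887 were low in DPC5352 (−2.79), DPC5360 (−2.76) and DPC5367 (−1.86), with the other 6 at −0.56 to −0.01. Other regions were low in fewer strains. ORFs 1158 to 1164 had a mean of −2.95 in DPC5360 and of −0.31 to 0.19 in the other 8. ORFs 1841 to 1847 stood at −2.61 in DPC5367 and −2.59 in CNRZ32, and ORFs 1091 to 1102 at −2.09 in DPC5367, −1.79 in DPC5360 and −0.96 in CNRZ32.

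The single run of DPC5394 and of DPC5607 was the same 8 ORFs, 1186 to 1193, with means of −2.64 and −2.50. The other strains stood at −0.41 to 0.19 there, apart from DPC5352, which was higher at 1.92. The arrays of CNRZ32, the lowest of these (−0.41), differed there, with the test channel at −1.14 from the array median on array 1 (6 ORFs measured) and −0.35 on array 2 (8 ORFs). In the deposited table, whose locus tags the files do not pair with the array, tags 1246 to 1250 were low in DPC5394 (−3.31), DPC5607 (−3.06) and also CNRZ32 (−2.53), and high in DPC5352 (2.36). Tags 2515 to 2517 were likewise low in DPC5394 (−2.83) and DPC5607 (−2.59) and high in DPC5352 (2.73), with CNRZ32 at −0.91. In DPC5394 and DPC5607 the test channel stood below its array median in these ORFs, by log2 values of −2.67 and −2.74 on the arrays of DPC5394 and of −2.64 in DPC5607. On the DPC5352 arrays the reference channel was low instead, at −2.68 and −2.66, against −0.45 to 0.16 on the other 16 arrays.

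**Figure D3:**
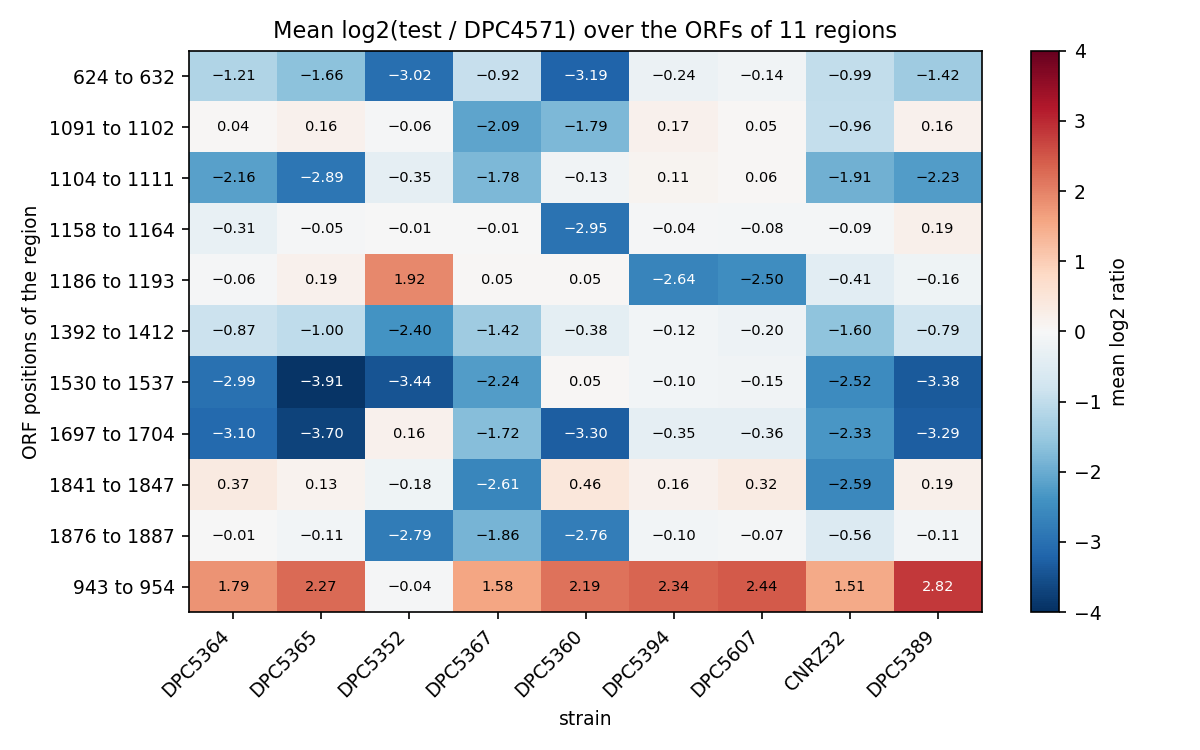
Mean log2 ratio of test strain over DPC4571 (colour and printed value) over the ORFs of the 10 largest regions with runs of lower ORFs and of ORFs 943 to 954, with regions as rows and strains as columns. ORFs 1186 to 1193 are low in DPC5394 and DPC5607 and high in DPC5352, and ORFs 943 to 954 are high in 8 strains and at −0.04 in DPC5352.

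The second question was which strains resembled each other. DPC5364, DPC5365 and DPC5389 had nearly the same lower ORFs. DPC5365 and DPC5389 shared 109 (Jaccard index 0.886, the shared ORFs over those lower in either), where independent lists would share 10.4. DPC5364 shared 115 with DPC5365 (10.0 for independent lists, Jaccard 0.846) and 103 with DPC5389 (11.7, Jaccard 0.844). CNRZ32 came next to these strains, with Jaccard indices of 0.541 to 0.570. DPC5394 and DPC5607 shared 14 ORFs (0.608 for independent lists, Jaccard 0.28), 8 of them the region at 1186 to 1193. The lowest Jaccard index was that of DPC5367 and DPC5394, 0.0149, with 3 ORFs shared where 2.94 were expected, and CNRZ32 and DPC5394 shared 2 where 1.96 were expected. A bias of the dyes that is particular to an ORF is shared by all arrays and would raise the overlaps of all pairs. DPC5394 and DPC5607 had Jaccard indices of 0.0226 to 0.0547 with DPC5364, DPC5365 and DPC5389. In ORFs 1530 to 1537 these 3 strains stood at −3.91 to −2.99, and DPC5394 and DPC5607 at −0.10 and −0.15. Both argue against such a bias as the main source of the likeness of the 3. Relative to each ORF's median over the strains, which also removes a difference that most strains share, the first 3 pairs shared 17, 14 and 8 ORFs. By the days in the headers, the median Jaccard index was 0.169 for 16 pairs of strains with no day in common, 0.357 for 14 pairs with 1 day and 0.343 for 6 pairs with 2, and the pair of DPC5364 and DPC5389 (0.844) had no day in common. In 26 of 36 headers the weekday is not that of the date, so these days are uncertain.

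**Figure D4:**
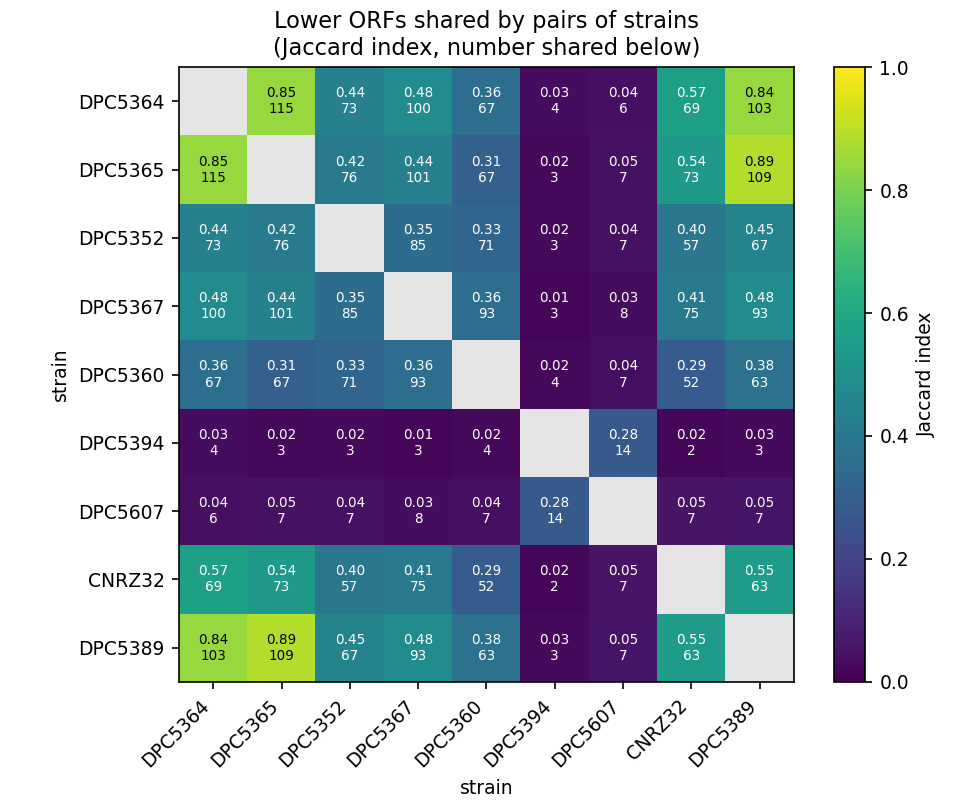
Jaccard index of the lower ORFs of each pair of strains (colour and upper value, from 0 to 1) with the number of shared lower ORFs below it. The highest indices, 0.844 to 0.886, lie among DPC5364, DPC5365 and DPC5389.

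Taking the 9 strains as samples of one group, limma on the strain means called 109 of 2159 ORFs lower than DPC4571 and 12 higher (Benjamini-Hochberg adjusted p under 0.05 and a mean log2 ratio of at least 1 in size). The strains were chosen isolates, so this test measures the spread between them, and it leaves out the spread of the reference. It also counts alike strains as independent samples, so its SE and p-values may be too small. Jaccard indices were 0.844 to 0.886 among DPC5364, DPC5365 and DPC5389, and DPC5394 and DPC5607 correlated at 0.693 across ORFs. The sign-flip test below shares this limit. A called ORF need not be low in every strain, and some with n = 9 were below 0 in only 6. OBSca009#0629, in the region at ORFs 624 to 632, had a mean log2 ratio of −2.73 (SE 0.384, n = 9, limma adjusted p = 0.00202) and was below 0 in 9 of 9 strains, with DPC5394 at −0.34 and DPC5607 at −0.84. OBSca009#0035 had a mean of −2.40 (SE 0.38, n = 9, limma adjusted p = 0.0033), also below 0 in 9 of 9 strains, with DPC5394 at −0.10. Leaving out each strain in turn gave 85 to 117 lower ORFs, loess and a threshold of 1.5 gave 69 each, and treat at 0.5 gave 28 lower and 7 higher. An exact sign-flip permutation test over the 9 strains cannot give a p below 0.00391. After adjustment its lowest p was 0.0609, so it called 0 ORFs in either direction, with 111 lower and 12 higher at an unadjusted p under 0.05. With the day of measurement of the second array as a block, 104 ORFs were lower and 12 higher. The mean over the 109 lower ORFs was −1.14 in the 4 strains of the day that included DPC5394 and DPC5607. It was −2.12 in the 5 strains of the other day, and 0 ORFs differed between the days after adjustment. Strains and days are confounded and the groups are small, so this 0 cannot speak against an effect of the day.

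Of the 12 higher ORFs, 11 lay side by side at numbers 943 to 954. Their mean log2 ratio was 2.82 in DPC5389, 2.44 in DPC5607, 2.34 in DPC5394, 2.27 in DPC5365, 2.19 in DPC5360, 1.79 in DPC5364, 1.58 in DPC5367 and 1.51 in CNRZ32, and −0.04 in DPC5352. In CNRZ32, 5 of the 11 ORFs were higher by the rule for a strain and they formed no run. The deposited table had runs of higher ORFs in 7 strains at locus tags 965 to 980, a numbering that the files do not pair with the array, with CNRZ32 at 0.47 and DPC5352 at 0.031. OBSca009#0952 had a mean of 2.77 (SE 0.389, n = 9, limma adjusted p = 0.00202) and OBSca009#0948 one of 2.40 (SE 0.313, n = 9, limma adjusted p = 0.00133), above 0 in 9 of 9 strains, with DPC5352 at 0.01 and 0.07. The ratios came with a low reference signal. In these 12 positions the DPC4571 channel stood at −3.20 to −1.51 from the array median on the log2 scale on the 16 arrays of the other 8 strains (median −2.64, the identical pair of DPC5607 included), and at −0.42 and −0.27 on the 2 arrays of DPC5352. The test channel of the 16 arrays was at −0.90 to −0.04. With ORFs kept only where the reference reached 4 times background, 4 ORFs were called higher.

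**Figure D5:**
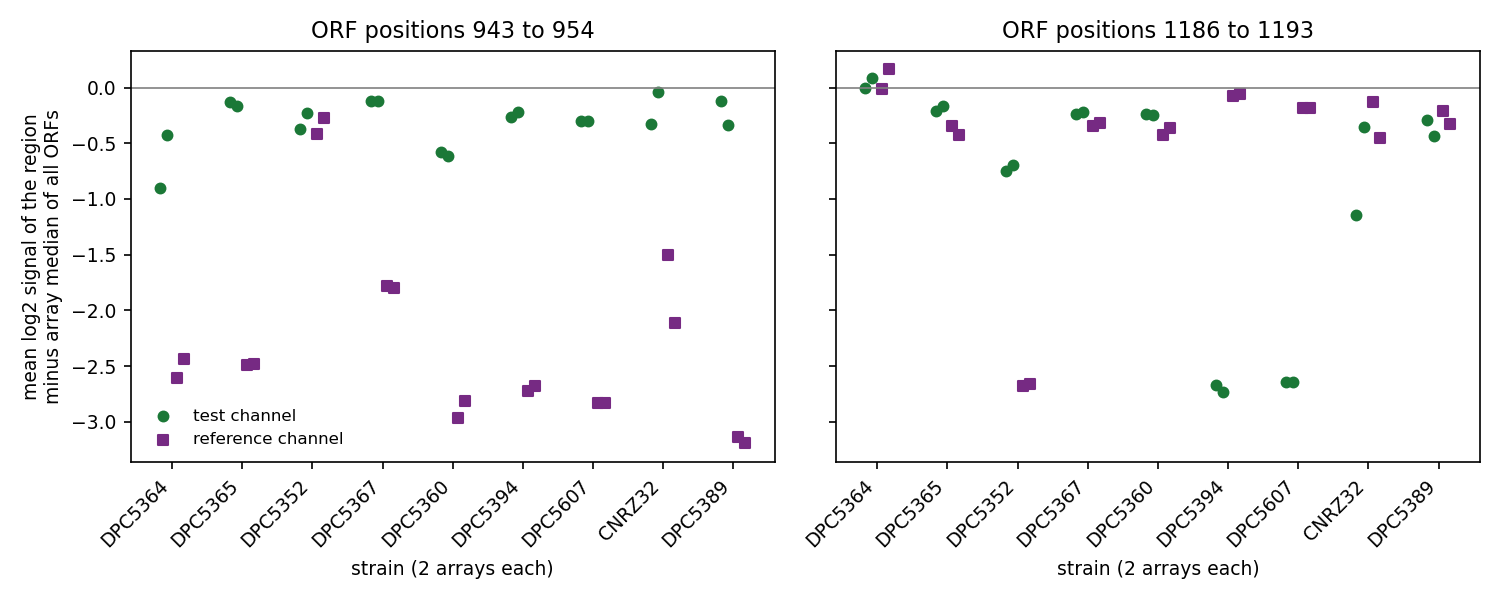
Mean log2 signal of ORFs 943 to 954 (left) and 1186 to 1193 (right) minus the median of all ORFs on that array, for the test channel (circles) and the DPC4571 channel (squares) of each strain's 2 arrays. The DPC4571 channel of the DPC5352 arrays sits at −0.42 and −0.27 on the left and at −2.68 and −2.66 on the right, apart from that of the other 16 arrays in both regions.

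No array carried DPC4571 DNA in both channels, so the reference channels of pairs of strains were set against each other by the same rule to give a background. The 36 pairs gave 1 to 176 calls per pair and direction, with a median of 40. DPC5394 had 29 lower ORFs and DPC5607 44, and the other 7 strains had 110 to 211. Counts are not on one scale, since the pairs measured a median of 1252 ORFs (837 to 1893), against 1775 in DPC5394 and 1958 in DPC5607. As shares of measured ORFs, lower calls were 0.61 to 10.6% in the pairs, 1.63% in DPC5394 and 2.25% in DPC5607. The other 7 strains had 6.29 to 11.2%. The pairs also compare 2 slides in the same dye, unlike a strain's ratio within 1 slide. Runs of 3 or more numbered 0 to 5 per pair and direction in this background, with a median of 0. The other 7 strains had 12 to 29 runs of lower ORFs, and DPC5394 and DPC5607 had 1 each, within that range. The reference channels of the DPC5352 arrays differed from those of the other 8 strains by 1.19 to 2.75 in ORFs 943 to 954 (median 2.08) and by −3.01 to −2.25 in ORFs 1186 to 1193 (median −2.49). Over the other 28 pairs the size of the difference had a median of 0.548 and reached 1.32 in ORFs 943 to 954, above 1 of the 8 DPC5352 pairs. In ORFs 1186 to 1193 it had a median of 0.205 and reached 1.48.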

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

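The differences between strains given here were noticed in the data and were not tested, since each strain was 1 sample. The tests of slide position over all neighbours and of reference hybridisation were written before their results were seen, and the test of local patches was chosen after.

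There were 18 ORFs lower in at least 1 strain and higher in another, all arrays of each strain on the same side, and 7 of them lay among the 8 ORFs at 1186 to 1193. The mean log2 ratio there was 1.92 in DPC5352 against −2.64 in DPC5394 and −2.50 in DPC5607. In spots outside the comparisons, RNA spike spots had a median test signal of 2.34 times background and production control spots of 2.25 times, above the 1.28 times of empty positions on 18 of 18 arrays.

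Lower ORFs lay in runs along the numbering. Reference hybridisation alone accounts poorly for the runs of 7 strains (12 to 29 each), since a pair of reference channels gave at most 5 runs and a median of 0 per direction. The 1 run each of DPC5394 and DPC5607 lies within that range. Run counts are not on one scale, as the pairs measured a median of 1252 ORFs and gave a median of 40 calls per direction. A position effect on the slide was to be excluded if slide neighbours with distant numbers correlated under 0.25 times as strongly as number neighbours in 7 strains, and 6 strains met this, so the planned bound was missed. A local patch of the slide is argued against in all 9 strains, because 0 of 2163 pairs of neighbouring numbers share a block of spots and yet they correlated more strongly than spots side by side with distant numbers, the lowest lower bound of the difference being 0.125 (bootstrap 95% interval). A position effect repeated in every block, or one of source plates, stays open, and so does the hypothesis that neighbouring ORFs differ together in the strains' genomes: the 133 runs of the deposited table come from the same hybridisations in an order that rises with the array numbering and do not test it.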

How the results depend on the processing

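The choices of the foreground median, of ORFs measured in all 9 strains, of leaving out CNRZ32, DPC5607 or DPC5352 and of the day of measurement were made after seeing the data; the other alternatives were fixed before. No paired analysis was possible because each strain was 1 sample. Tests of gene groups, their rotation, their count at 3 strains and runs without transposases were not run, as the files do not pair identifiers with products. limma gave no value relative to each ORF's median, which removes the mean it tests, nor for the mean of the 2 arrays, which it uses already. Of 429 counts under alternatives, 327 stayed within 1.5 times and 102 did not; the cause was not tested unless the construction shows it. Signal over background of 8.002 to 56.7 and 1 sample per strain limit what a small count can show.

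Runs beyond shuffles held under 17 alternatives tested, with 46 to 230 runs (one-sided permutation p = 0.001, the smallest that 1000 shuffles can give). Runs of 2 or more numbered 230 and of 5 or more 46, by construction. Of the 1078 lower calls, 838 were also called with loess, 1075 with background subtraction, 810 at 1.5, 999 with marked spots kept and 425 relative to each ORF's median. Without CNRZ32, DPC5607 or DPC5352, 387, 379 or 385 ORFs were lower in at least 1 strain, and runs numbered 124, 135 or 123.

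The deposited table, which has 1 value per strain and so no second array to pass, had 830 ORFs lower in at least 1 strain. Lower and higher numbered 196 and 83 in DPC5364, 157 and 56 in DPC5365, 141 and 87 in DPC5352, 285 and 110 in DPC5360, 112 and 51 in DPC5394, 206 and 72 in DPC5607 and 325 and 101 in CNRZ32. By the rule of both arrays on the scanner values, not in that table, 159 of the ORFs measured in all 9 strains were lower in at least 1.

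Relative to each ORF's median over strains, 0 ORFs were lower in all 9 strains and there were 48 runs. Lower and higher ORFs numbered 31 and 31 in CNRZ32, 81 and 45 in DPC5352, 24 and 13 in DPC5364, 60 and 2 in DPC5365, 105 and 59 in DPC5367, 22 and 9 in DPC5389, 14 and 87 in DPC5394 and 35 and 99 in DPC5607. DPC5364 and DPC5365 shared 14 lower ORFs, DPC5364 and DPC5389 8, and DPC5365 and DPC5389 17. The highest mean among the low strains changed sign in ORFs 1530 to 1537 (0.38), 1697 to 1704 (0.54) and 624 to 632 (0.026), since most strains were low there.

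With loess within arrays 69 ORFs were lower by limma and 0 in all 9 strains. Lower and higher numbered 36 and 19 in CNRZ32, 12 and 14 in DPC5394, 15 and 21 in DPC5607 and 109 and 19 in DPC5389, and 15 were higher in DPC5364. Centred on the mode, DPC5364 had 163 lower and 13 higher and DPC5352 8 higher. With normexp, lower and higher numbered 14 and 7 in DPC5394 and 163 and 169 in DPC5607. By the mean of the 2 arrays CNRZ32 had 171 lower. With marked spots kept DPC5607 had 24 lower and 44 higher. With the foreground median DPC5607 had 103 lower and 35 higher, and 34, 46, 45 and 22 were higher in DPC5352, DPC5360, DPC5364 and DPC5365. With the reference at 4 times background, 4 ORFs were higher by limma, 4 in DPC5365, and DPC5394 had 28 lower and 6 higher.

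At a threshold of 1.5, which is stricter by construction, 69 ORFs were lower by limma and 0 in all 9 strains, and reference pairs gave a median of 15 calls. Lower and higher numbered 69 and 40 in CNRZ32, 134 and 24 in DPC5367, 8 and 9 in DPC5394, 8 and 10 in DPC5607, 102 and 7 in DPC5364 and 95 and 14 in DPC5389, and 5 and 9 were higher in DPC5352 and DPC5360. At 0.75, 622 ORFs were lower in at least 1 strain, 26 higher by limma, and reference pairs gave 75.5 calls. Lower and higher numbered 58 and 66 in DPC5394, 168 and 158 in DPC5607, 146 and 44 in DPC5352, 196 and 59 in DPC5360, 296 and 251 in DPC5367 and 119 and 99 in DPC5389, and 67 and 24 were higher in DPC5364 and DPC5365.

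With a single array, higher ORFs ranged from 134 to 157 in CNRZ32, 40 to 41 in DPC5360, 41 to 47 in DPC5364, 13 to 34 in DPC5365, 60 to 61 in DPC5389 and 15 to 22 in DPC5394, and lower ORFs from 183 to 245 in CNRZ32, above the counts that need both arrays, by construction. treat at 0.5 gave 28 lower and 7 higher. The exact sign-flip permutation test called 0 and 0, with an adjusted p of 0.0609 at best, since its smallest p is 0.00391. Under limma's alternatives other than these, 102 to 119 ORFs were lower where no strain was left out, apart from 69 with loess and 69 at 1.5.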

Other observations

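The tests on DPC5394 and DPC5607 and the tests of dye bias, of copies in the test strains and of less of ORFs 943 to 954 in the reference were chosen only after the results were seen, while the test of another reference DNA was written before. Tests by percentile among other windows of the array, also written before, set different ORFs' signals against each other and are not used.

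Further regions of the numbering separated strains. ORFs 1104 to 1111 had their lowest mean in DPC5365 (−2.89), with DPC5389 at −2.23, DPC5364 at −2.16, CNRZ32 at −1.91 and DPC5367 at −1.79, while DPC5352, DPC5360, DPC5394 and DPC5607 stood at −0.35 to 0.11. ORFs 624 to 632 were lowest in DPC5360 (−3.19) and DPC5352 (−3.02), with DPC5394 and DPC5607 at −0.24 and −0.14 and the other 5 strains at −1.66 to −0.92. ORFs 569 to 574 were low in DPC5352 (−3.13) and DPC5360 (−2.43), and ORFs 84 to 89 in DPC5360 (−2.79), CNRZ32 (−2.20) and DPC5367 (−1.496). In the deposited table, whose locus tags have their own numbering, tags 1984 to 2003 had means of −3.81 to −1.29 in 7 strains, with DPC5394 at −0.12 and DPC5607 at −0.35.

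The last 200 ORFs of the numbering, 1965 to 2164, were a window chosen after the values were seen. Their mean log2 ratios were 0.55 in DPC5394, 0.53 in CNRZ32, 0.51 in DPC5389 and 0.48 in DPC5607. By the headers, the second arrays of these 4 strains share a day. The 5 strains of the other day had 0.34 (DPC5367), 0.22 (DPC5352), 0.16 (DPC5364), 0.07 (DPC5360) and 0.02 (DPC5365). Before that window the means ran from −0.19 to −0.01.

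The headers of a strain's 2 arrays named different images and days for all 9 strains, including DPC5607, whose arrays were identical at 4608 of 4608 spots. The difference between the 2 copies of an ORF on the slide, test channel, correlated between the arrays of a strain at 0.325 to 1.0 (median 0.875, across ORFs) and between arrays of different strains at a median of 0.144 and at most 0.569. Background signals of the test channel correlated at 0.854 to 1.0 within strains and at a median of 0.320 between them. For CNRZ32 the background of the reference channel correlated at 0.229 between its arrays.

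DPC5394 and DPC5607 had the lowest counts of lower ORFs by the rule of both arrays; by count this was lost under 5 of 15 alternatives, in 1 of them (the deposited table) by DPC5394 too, and by share of measured ORFs under 4, by DPC5607 alone. Compressed ratios on these arrays stay open: against them, the region at 1186 to 1193 had a mean of −2.50 or lower in both, and ORFs 943 to 954 stood at 2.34 and 2.44, among the 3 highest of 9 strains, but 1186 to 1193 is their only run of lower ORFs, their lower ORFs had medians of −1.22 and −1.13, and 8 ORFs of each were lower at a threshold of 1.5. Test DNA mixed with an equal or larger amount of DPC4571 DNA could not give log2 ratios as low as the 5 lowest ORFs of each strain, which averaged −2.75 or lower, and a smaller admixture stays open. Fewer measured ORFs do not account for the counts, since the higher of their shares was 2.25% of measured ORFs. A genome closer to that of DPC4571 is a hypothesis that was not tested otherwise.

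ORFs 943 to 954 had a high mean in 8 strains, with 5 of 11 ORFs called in CNRZ32, and not in DPC5352. Dye bias shared by all arrays is argued against by the reference channels, all Cy5, which in these ORFs were 2.08 higher on the DPC5352 arrays than on the others (median over 8 pairs, 7 of them above the highest of the other 28 pairs), and more copies in the 8 test strains than in DPC5352 by their test level, at most 0.18 above that of DPC5352. The reference level on the DPC5352 arrays lay at least 1.09 above that on each of the other 16 arrays, consistent with less of this region in the reference DNA of those 16. A hypothesis for DPC5352 is that other reference DNA was on its arrays, and a second difference was predicted in ORFs 1186 to 1193. There its reference channel was −2.49 from the others (median over 8 pairs), low where the test DNA of DPC5394 and DPC5607 was low. This is not a separate check, since the ratio of 1.92 in DPC5352 already needed a high test or a low reference signal. It adds that the test channel was not high there (−0.75 and −0.70 from the array median). If so, the counts of DPC5352 may describe a comparison with another strain, and the labels give no such exchange. Which reference departs from DPC4571 cannot be told from these levels. The reference was low in ORFs 943 to 954 on the other 16 arrays and in ORFs 1186 to 1193 on those of DPC5352. The counts of the other 8 strains therefore carry the same doubt.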
